A study of Bifidobacterium breve 12L and Bifidobacterium adolescentis
Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium bifidum PRL2010
Bifidobacterium breve 12L and Bifidobacterium longum subsp. infantis ATCC 15697 = JCM 1222 = DSM 20088
Bifidobacterium breve 12L with 5 samples.

How the data were processed

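RNA from mice and from a culture was measured on 2-colour arrays with probes for 4 bifidobacteria. Per the labels' protocols, RNA was reverse transcribed and amplified, and cDNA was labelled with Cy5 or Cy3. The spot intensity values were deposited by the authors as scanner output, with 37603 spots per array used here, of which 36152 were probes of the 4 species, 1417 control spots and 34 probes of other origin. Other spots of the array were not analysed here. Per the file headers the scans were extracted with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 10.10 and limma without a version. The conflict was not resolved. The scanner software's log10 ratios in the deposited files were not used here. The deposited log2 values of the series table cover 1825 B. breve genes. How the authors scaled and centred them is not given in the sources used here. Against the scanner values they had r from 0.963 to 0.991 with the mean of the turned arrays and slopes from 0.953 to 1.02. The medians of the authors' deposited log2 columns were -0.29 for mice against culture, 0 for 4 species, 0.05 with B. infantis, 0.03 with B. bifidum and 0 with B. adolescentis.

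Signals were corrected with limma 3.58.1 in R 4.3.3 (normexp on mean foreground and median background, offset 50). Loess was fitted within each array on the B. breve probes, with all other spots at weight 0. Outlier spots were left out and saturated spots kept. The culture channels had 199 and 671 saturated probes, and the mouse-derived channels 1 to 118. Each array was turned by the sign of its correlation with the authors' values. Array II held the first-named RNA in Cy5 except in the comparison with B. adolescentis, where array I did. This orientation was taken from values and not from a label, and was tested afterwards on the mono-associated channels of different slides. A gene was measured where at least 50% of its probes were well above background in 1 or both channels on both arrays. Its value was the median over these probes, then the mean of the arrays. Both arrays of a comparison lay on 1 slide and each comparison on a slide of its own, so slide and comparison cannot be told apart. Where a gene was not well above background at any probe in 1 RNA on both arrays, its fold is a bound from channels normalised by loess and Aquantile.

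The rule for named genes, fixed before the data were examined, took at most 2 identifiers that rose and 2 that fell in each comparison, with the largest mean ratio among genes past the size rule of which at least 80% of the measured probes had the gene's direction. A gene with 1 measured probe meets this last condition by construction. The 27 gene lists fixed beforehand were matched on product text and could not be used, since 0 of the B. breve identifiers matched the reference table, which describes another B. breve strain (assembly ASM102517v1).

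Intraclass correlations of the probes of a gene were computed for genes with at least 3 probes, with and without removal of the mean at each GC content, and their spread by 200 bootstrap draws of genes. Probes were matched to those of other species with blastn 2.17.0, and 2927 B. breve probes with at least 45 identical bases were left out in an alternative. Wilson intervals, shuffles and simulations used Python with pandas, numpy and scipy. The gene step was tested on simulated normal ratios built from the real spread of the probes, with the same spread on both arrays. The unchanged genes so simulated were more spread than the measured genes, so their rates are no reference for the measured counts. In mice against culture, on 1788 genes, the gene step recovered 88% of genes changed by 2 (log2) and 31% of those changed by 1, and called 5.35% of unchanged genes. In the comparisons between mouse-derived RNAs it recovered 71.1% of genes changed by 2 with 4 species, 72% with B. infantis, 74% with B. bifidum and 74% with B. adolescentis, and called 17.0%, 19.7%, 24.8% and 25.1% of unchanged genes. A criterion of that test was loosened after a first run, since some genes changed by 1 or 1.5 turned direction through probe noise. A step of the overlap test was also corrected after its first result, as stated with that test. The genes of other species, GC adjustment, weighting by measured probes, centring of each species and the bound on the shared control were chosen after seeing the data. The reading of the shared-control test was changed after its values were seen, from excluding that control to leaving it open, because the simulation assumes the size of the control's part. The planned test of a culture profile in mice, on r over gene means, was replaced after its value was seen by r over different probes of a gene.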

Results

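The series measured transcripts of Bifidobacterium breve 12L, a gut bacterium, in mice that received it alone or together with other bifidobacteria. Groups of 5 female BALB/c mice aged 3 months were given bacteria by mouth in 5 daily administrations of 20 µl. The inocula named in the labels were B. breve 12L alone (mono-association), all 4 species, and B. breve with B. longum subsp. infantis ATCC15697, B. bifidum PRL2010 or B. adolescentis 22L. The array carried 60-base probes for the genes of all 4 species, with 8697 probes for 1825 genes of B. breve. Each of the 5 comparisons was 1 sample, hybridised to 2 arrays with Cy5 and Cy3. Whether RNA of several mice was pooled is not given in the sources used here, so each comparison was treated as 1 replicate and no p-value was computed. Ratios of named genes are means of both arrays, in most cases with the SD of the arrays, and folds given as bounds have no SD. The number of arrays limits the precision of every value.

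The files and the reference table paired no gene name, product or position with the B. breve identifiers, so genes are given by identifier and gene groups could not be described. A gene counted as higher or lower when both arrays gave a log2 ratio of at least 1 in that direction. The labels put the first-named RNA in Cy5 on every array, but the log ratios of the arrays of each comparison correlated negatively over all probes, with r from -0.756 to -0.445. The directions below come from the sign of each array's correlation with the authors' deposited values and the order of the RNAs in the titles. They were checked on the mono-associated RNA, which by the labels is on all 5 slides. So turned, its channels agreed between slides with r of at least 0.802 at equal dye, and the other channels of a slide had r of at most 0.752 with them, higher on 0 slides. Between culture and mouse-derived channels r was 0.345 to 0.490.

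B. breve probes were brighter than those of the other species with RNA from the culture, and hardly so with RNA from mice. In the culture channels 91.7% and 98.8% of the B. breve probes were well above background, against 65.2% and 78.5% of the B. adolescentis probes, which have the same median GC content of 53.3%. In the 18 mouse-derived channels the share ranged from 7.03% to 48.6% for B. breve and from 6.83% to 48.7% for B. adolescentis. B. bifidum probes, with a median GC content of 56.7%, reached up to 60.8% there. At equal GC content B. breve probes exceeded those of the other species together by a median of 0.70 and 1.15 (log2) in the culture channels, and by 0.01 to 0.07 in the mouse-derived channels, where the sign was positive in all 18. Relative to B. breve in the mouse-derived channels, B. infantis probes alone lay from -0.03 to 0.03. B. bifidum probes lay from -0.14 to -0.02 and B. adolescentis probes from -0.11 to -0.01. The excess in culture depended on GC content. On array I it was 2.27 for probes of 40% to 45% GC and 0.25 for those of 60% to 65% GC. On array II it was 0.83, 0.89 at 45% to 50% GC, and 0.25.

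**Figure D1:**
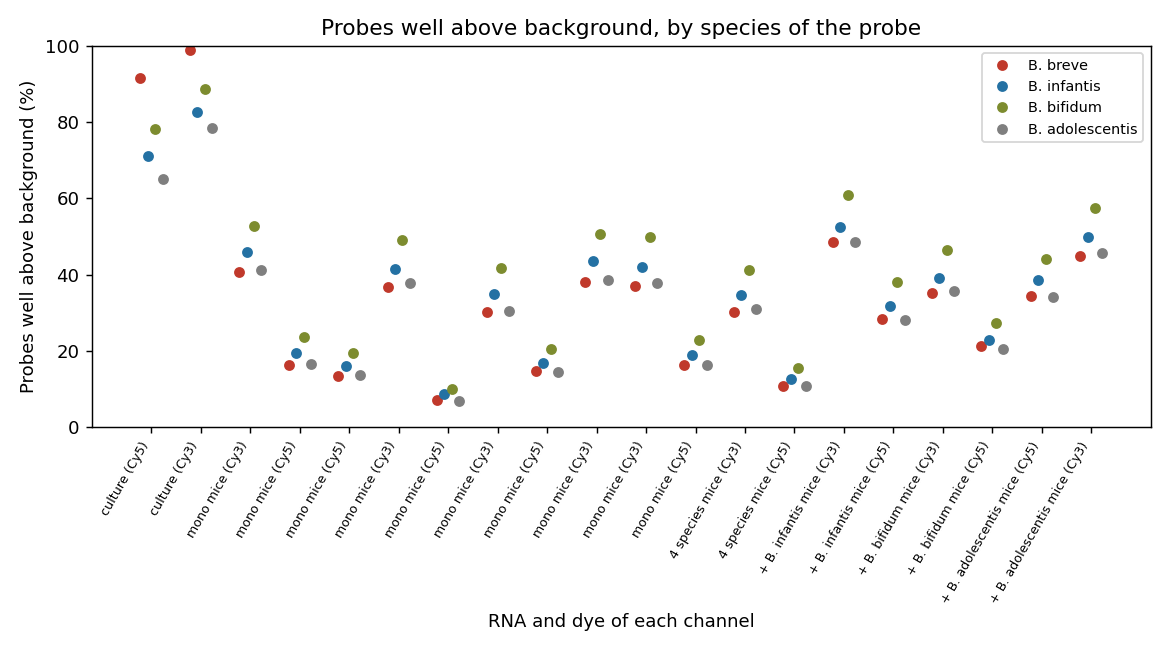
Share of probes well above background (vertical axis, percent) in each of the 20 channels (horizontal axis, RNA and dye), with 1 point per species of the probe. B. breve probes lie above the others in the 2 culture channels, at 91.7% and 98.8%, and beside those of B. adolescentis in the 18 mouse-derived channels.

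The probes of an added species were no brighter in the mice that received it. In the mice given all 4 species, the log2 ratios to mono-associated mice were -0.02 for B. infantis, -0.03 for B. bifidum and -0.02 for B. adolescentis relative to B. breve probes, as means of 2 arrays without loess. In the mice given 1 added species the ratio was 0.04 ± 0.09 (SD, n = 2 arrays) for B. infantis, -0.01 ± 0.04 for B. bifidum and -0.01 ± 0.03 for B. adolescentis. The labelled difference between these groups was thus not detectable on the species' own probes, and the B. breve ratios below are to be read beside those of species given to neither group. No RNA of the added species alone was hybridised, so whether their probes detect them was not shown.

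The comparison of mono-associated mice with culture in mouse-food medium addressed which B. breve genes differ between the mouse and the medium. Of 1788 measured genes, 15 were higher and 10 lower in mice, and 0 passed in size in opposite directions on the arrays. The share past the rule was 1.40% (95% Wilson interval 0.949% to 2.06%) for B. breve, and 4.67% (4.11% to 5.30%) for the 4837 genes of the 3 species in neither RNA. At equal numbers of measured probes the ratio of these shares was 0.374 (95% bootstrap range 0.225 to 0.554). Part of that comes from the loess on B. breve probes, which left the median mean ratios of the other species at 0.30 to 0.31, with 196 genes higher and 30 lower. With each species centred on each array the shares were 1.45% and 3.47%, with 125 of the other genes higher and 43 lower, which is a ratio of 0.419, or 0.535 (0.333 to 0.785) at equal numbers of measured probes. Centring moves the median only, and these values still come from the loess fitted on B. breve probes alone. Without loess 171 B. breve genes passed with median centring and 242 with processed signals. Ratios below 1 in this comparison therefore do not show that B. breve genes changed less than those of absent species. Without probes that match another species the shares were 4.30% (3.42% to 5.40%) for B. breve and 7.09% (6.39% to 7.86%) for the absent species. Their ratio was then 0.55 (0.43 to 0.70) at equal numbers of measured probes. Simulated unchanged genes passed at 5.35%, but the simulation gave both arrays the same spread, which the real arrays did not have. Their median size was 0.42 (log2), against 0.35 for the measured genes, so this rate is no reference for the counts. The gene BrMilk_1369 was not well above background in mice at any of its 5 probes, and its bound was 7.13-fold lower than in culture. Its log2 ratios were -4.20 on array I and -2.36 on array II, so array II alone gives a smaller fold than that bound. All 5 probes of BrMilk_1369 were lower in mice. BrMilk_0471 was lower by a mean log2 ratio of -2.18 ± 1.12 (SD, n = 2 arrays) over 4 probes, of which 1 of 8 spots was well above background in mice, so the ratio is against a signal near background. The higher genes had less even probes. BrMilk_0935 had a mean of 3.11 ± 0.63, with its 3 measured probes from 0.23 to 3.55 and 0.30 without the filter on dim probes, and BrMilk_0506 one of 2.58 ± 0.62, with 3 probes from 1.31 to 3.68 and 1.25 without that filter. Genes with consecutive numbers had related ratios, with r = 0.20 across 1717 neighbouring pairs, outside the range of -0.05 to 0.04 that held 95% of 1000 shuffled orders. Genes are not independent replicates. The count depended on the array and the scaling. It was 450 on array I alone, 38 on array II alone, 5 higher with 10 lower without the filter on dim probes, 9 higher with 162 lower under median centring, and 29 higher with 4 lower among 112 genes with probes well above background in both channels. The ratios are relative to a loess on B. breve probes and do not show whether B. breve transcripts as a whole changed.

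**Figure D2:**
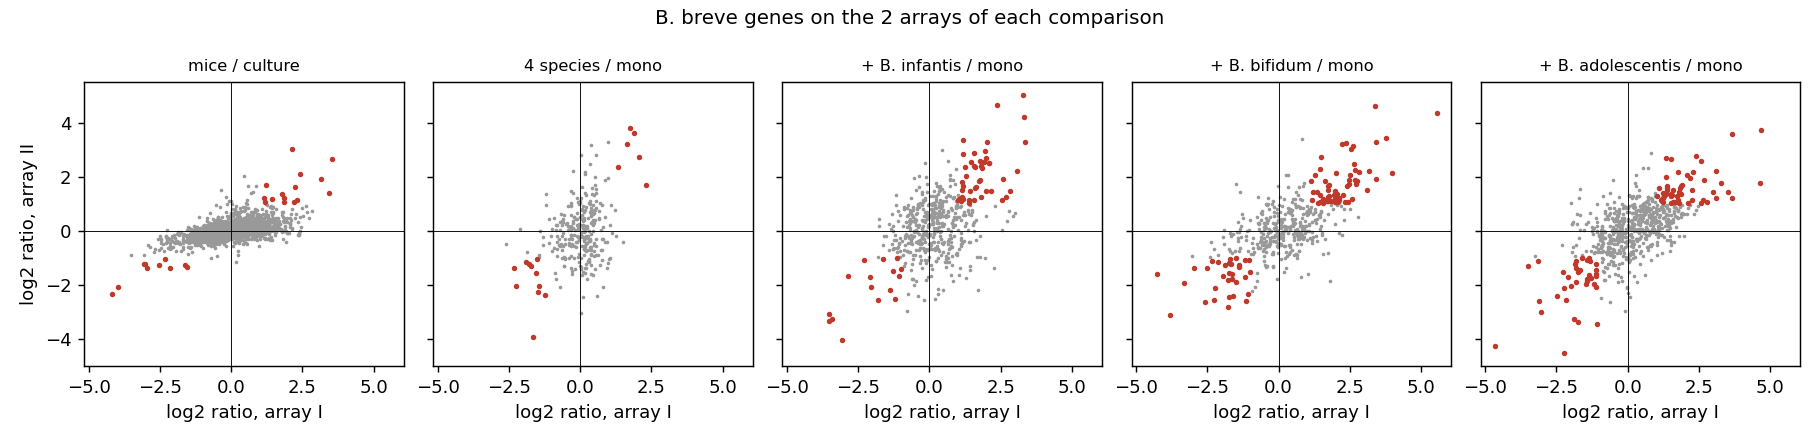
Log2 ratios of measured B. breve genes on array I (horizontal axis) and array II (vertical axis) for each comparison, with 1 point per gene and genes past the size rule in red. Ratios on array II of mice against culture span less than on array I, and 25 genes passed there.

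The mice given all 4 species were compared with mono-associated mice to ask how the community changes B. breve transcripts. Only 294 B. breve genes were measured, of which 6 were higher and 11 lower, and 1 passed in opposite directions. BrMilk_1405 was not well above background in the 4-species mice and was at least 2.55-fold lower over 3 probes. BrMilk_0218 was lower at -1.75 ± 0.43 and BrMilk_0020 higher at 2.42 ± 1.09, each on 1 measured probe and with 1 of 4 spots well above background in the lower RNA. The measured probe of BrMilk_0218 matches a probe of another species, and without such probes the gene has no value, while BrMilk_0020 keeps 2.42. BrMilk_0571 was higher at 1.99 ± 0.44, with 3 probes from 0.13 to 3.00. Without the filter on dim probes BrMilk_0020 had 1.17, BrMilk_0571 had 0.43 and BrMilk_0218 had -0.94, and in the authors' deposited values the last 2 had 0.94 and -0.84. The share of B. breve genes past the rule was 5.78% (95% Wilson interval 3.64% to 9.06%), against 6.53% of the genes of the other species. Array I alone gave 37 genes and array II alone 93. No filter on dim probes left 0 genes higher and 1 lower, and with probes well above background in both channels 1 of 25 was higher and 0 lower.

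With B. infantis added, 45 of 504 measured B. breve genes were higher and 16 lower than in mono-associated mice, and 8 passed in opposite directions. BrMilk_1546 was at least 8.85-fold higher on its 1 probe, which matches a probe of another species, so the gene has no value without such probes. BrMilk_1771 was higher at 3.76 ± 0.62 (SD, n = 2 arrays), with 3 probes from 1.15 to 5.03 and 1 of 10 spots well above background in mono-associated RNA. BrMilk_0796 was lower at -3.55 ± 0.69, with 3 probes from -4.70 to -0.22, and BrMilk_0533 at -3.43 ± 0.12 on 1 probe, with 1 of 4 spots well above background in the mice with B. infantis. Without the filter on dim probes BrMilk_1771 had 1.15, BrMilk_0796 had -0.92 and BrMilk_0533 had -1.61. The share past the rule was 12.1% (Wilson interval 9.54% to 15.2%). It was 12.0% (10.3% to 13.9%) for the genes of B. bifidum and B. adolescentis, which neither group had received. Array I alone gave 145 genes, array II alone 166, and median centring 100 higher and 4 lower. No filter on dim probes gave 17 higher and 8 lower, and among 22 genes with probes well above background in both channels 1 was higher and 7 lower.

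With B. bifidum added, 57 of 430 measured B. breve genes were higher and 32 lower, and 4 passed in opposite directions. BrMilk_0899 was higher at 4.95 ± 0.85 and BrMilk_1862 at 4.00 ± 0.85, each on 1 measured probe, with 1 and 2 of 4 spots well above background in mono-associated RNA. BrMilk_1789 was lower at -2.60 ± 0.03 with 2 probes at -3.70 and -1.50, and BrMilk_0297 at -2.30 ± 0.76 with 3 probes from -4.56 to -0.06 and 2 of 10 spots well above background in the mice with B. bifidum. Without the filter on dim probes these 4 genes had 2.69, 1.80, -0.80 and -0.11. The share past the rule was 20.7% (17.1% to 24.8%) for B. breve and 16.4% (14.3% to 18.7%) for the species given to neither group. At equal numbers of measured probes the ratio of these shares was 1.24 (95% bootstrap range 1.02 to 1.57), and 1.14 (0.97 to 1.34) without probes that match another species. Array II left out gave 181 genes, no filter on dim probes 16 higher and 4 lower, and probes well above background in both channels 4 higher and 10 lower of 49.

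With B. adolescentis added, 54 of 666 measured B. breve genes were higher and 36 lower, and 3 passed in opposite directions. BrMilk_1248 was higher at 3.61 ± 0.05, with 2 probes at 3.11 and 4.11, and BrMilk_1097 at 4.20 ± 0.68, with 3 probes from 0.03 to 4.96 and 2 of 10 spots well above background in mono-associated RNA. BrMilk_0533 was lower at -4.46 ± 0.27 on 1 probe, with 1 of 4 spots well above background in the mice with B. adolescentis, and BrMilk_0990 at -3.04 ± 0.03 with 3 probes from -8.10 to -0.03. Without the filter on dim probes BrMilk_1097 had 0.21, BrMilk_0533 had -2.22 and BrMilk_0990 had -0.31. The share past the rule was 13.5% (11.1% to 16.3%) for B. breve and 12.7% (11.3% to 14.2%) for the species given to neither group. Array I alone gave 237 genes and array II alone 170, median centring 119 higher and 16 lower, processed signals 142 and 53, and no filter on dim probes 16 and 7. Probes well above background in both channels gave 3 higher and 5 lower of 71, and B. breve genes centred on each array 38 higher and 47 lower.

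**Figure D3:**
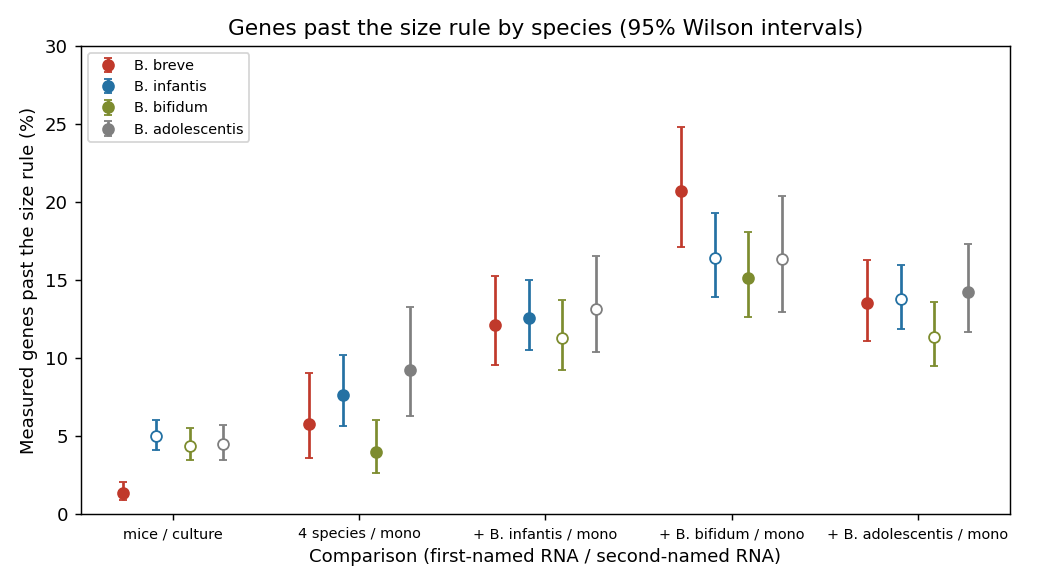
Share of measured genes past the size rule (vertical axis, percent) by comparison (horizontal axis) and species, with 95% Wilson intervals that cover counting error only. Open points are species given to neither group. In the comparisons with 1 added species the B. breve shares are 12.1%, 20.7% and 13.5%, beside 12.0%, 16.4% and 12.7% for the absent species together.

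Across the comparisons with mono-associated mice, 33 B. breve genes passed in the same direction in at least 2, 8 in at least 3 and 1 in all 4. The last, BrMilk_0533, was lower with log2 ratios of -1.51, -3.43, -2.19 and -4.46, each on 1 of its 2 probes. BrMilk_0210, BrMilk_0289 and BrMilk_1730 passed in opposite directions in 2 comparisons, and are named because their count was small. The comparisons have the mono-associated RNA in common. Over the 6 pairs, 15 shared higher and 37 shared lower calls stood beside 5.22 and 5.27 expected of independent lists, and 16 and 16 in simulations of unchanged groups sharing that control. The correlation across genes was 0.32 to 0.44 for B. breve. It was 0.23 to 0.49 for the genes of the other species and the medians of the simulations were 0.15 to 0.33, where the control was assumed to hold an equal part of the reproducible variance. The ranges that held 95% of the simulations ran from 0.02 to 0.42 over the pairs, and 1 of the 6 observed values lay within the range of its own pair. The covariance was 0.27 to 0.42, against simulated medians of 0.11 to 0.30. With 1 sample per comparison the controls could not be split, and part of the excess may come from the shared control.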

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

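The tests of RNA from other sources, of array noise, of GC content, of an array blind to species, of the shared control and of different probes of a gene were chosen after the result they bear on was seen, as were the shares of absent species.

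Genes of B. infantis, B. bifidum and B. adolescentis lay outside the B. breve measurement and passed the size rule in each comparison. The counts were 226 genes in mice against culture, 86 with 4 species, 255 with B. infantis, 280 with B. bifidum and 335 with B. adolescentis. In opposite directions in 2 of the comparisons with mono-associated mice were 3 B. breve genes. That difference was not tested.

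The first pattern weighed is the genes past the rule between mouse-derived RNAs. Array noise is argued against, since the ratio of opposite to same-direction genes was 0.0623. With the genes of array II shuffled this ratio was 0.854 to 0.961 over the comparisons. Same-direction genes then reached at most 14, 40, 42 and 46, against 17, 61, 89 and 90 observed. Species given to neither group passed nearly as often, with a B. breve share at most 1.26 times theirs. RNA from a source other than the 4 bifidobacteria would give such shares. They cannot tell it from B. breve RNA on the absent species' probes, since B. breve culture RNA put 65.2% to 88.6% of these well above background. Without probes matching other species the ratio of the shares rose to between 1.37 and 1.38, and at equal numbers of measured probes it was 1.08 to 1.14. Changed B. breve transcripts as the main source stay open by the test set beforehand. The excess in agreement of the probes of a gene over absent species ran from -0.063 to 0.0064 ± 0.0255 (bootstrap SD), with an upper bound of 0.0574 over the limit of 0.05. The agreement of B. breve probes itself was -0.010 ± 0.025 with B. infantis, -0.015 ± 0.029 with B. bifidum and 0.016 ± 0.019 with B. adolescentis, each within its SD of 0. Simulated normal ratios with no gene effect put 17.0% to 25.1% of unchanged genes past the rule in these comparisons, where 5.78% to 20.7% were observed. The simulated genes were more spread than the measured ones, with median sizes of 0.6427 to 0.8273 (log2) against 0.4275 to 0.605. The simulation therefore cannot show whether probe noise accounts for the calls.

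The second pattern is that B. breve probes were hardly brighter than others in mouse-derived RNA. GC content is argued against, since the largest GC-matched difference from the other species together was 0.0677 (log2), though it was above 0 in all 18 channels (from 0.0068). Relative to B. breve, B. bifidum probes lay from -0.140 to -0.0173 and B. adolescentis probes from -0.114 to -0.0101. B. infantis probes lay from -0.0255 to 0.0289, on both sides of B. breve. An array blind to species is argued against too for the B. breve probes, since the smaller difference in culture was 0.701. No RNA of the other species alone was hybridised, so the same was not shown for their probes. The planned test of a culture profile, an r over gene means that lay -0.114 ± 0.0297 from the highest of the other species, decides nothing, since r between probes within genes was higher still (0.408 against 0.317 for B. breve, 0.470 to 0.479 against 0.411 to 0.432 for the others). Over different probes of a gene r was 0.00836 ± 0.00702 between culture and mono-associated mice and 0.149 between the culture arrays. This argues against a B. breve signal in mice that carries the culture profile as plainly as the culture arrays do. The culture channels were brighter, so 0.149 is no yardstick for dim RNA. The agreement of the probes of a gene was 0.137 and 0.173 in culture and -0.0025 to 0.0382 in mice, which does not measure likeness to the culture profile. These values may reflect little B. breve RNA in the mouse-derived samples, and how little could not be measured.

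The third pattern is the correlation among the comparisons with mono-associated mice. It lay above the simulated range in 5 of the 6 pairs, but the size of the control's part was assumed there, and in 0 pairs did the covariance exceed the lower reproducible variance by over 2 SD, so the shared control stays open. The test of a shared response of B. breve gave a mean excess of -0.0121 ± 0.0511 over the highest other species. Its upper bound of 0.0902 lay below the limit of 0.1, which met the criterion set beforehand for no such response. The test cannot exclude a response, since B. breve RNA on the other species' probes would raise their correlations too. Some of those species were also given to the mice compared. The margin is narrow. The spread was first computed as the mean over single pairs, 0.0817, which gives a bound of 0.151, above the limit. It was then corrected to the spread of the mean that had been written beforehand.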

How the results depend on the processing

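The counts depended on the processing, and the cause was not tested. Counts are given in the order mice against culture, 4 species, B. infantis, B. bifidum, B. adolescentis, then genes shared by at least 2 comparisons, where they moved over 1.5 times from 25, 17, 61, 89, 90 and 33. Without background correction 58 genes passed in culture, 23 with B. infantis, and 19 were shared. Processed signals gave 242, 46, 120, 137, 195 and 68. Median centring gave 171 in culture and 104 with B. infantis. Without the filter on dim probes there were 15, 1, 25, 20, 23 and 10. Probes above background in both channels gave 1 with 4 species, 8, 14, 8 and 5 shared. The mean of the probes gave 88 in culture. The size rule on the mean of the arrays, with the same sign on both, gave 141, 37, 109 with B. infantis, 166 with B. adolescentis and 61 shared. Without probes matching other species there were 70, 50, 125, 168, 171 and 95. The authors' values gave 246, 33, 134, 139 with B. adolescentis and 63 shared. Leaving out 1 array gave 38 to 450, 37 to 93, 145 to 166, 130 to 181, 170 to 237, and 83 to 87 shared. Scaling also moved the split of higher and lower genes: in culture 15 and 10 became 106 and 136 with processed signals, 9 and 162 with median centring, 13 and 13 with loess on all species and 40 and 206 in the authors' values, as well as 5 and 10 without the filter on dim probes and 68 and 73 on the mean of the arrays; with B. infantis 45 and 16 became 104 and 16, and 100 and 4; with B. adolescentis 54 and 36 became 142 and 53, and 119 and 16. The 4-species split of 6 and 11 became 16 and 17 in the authors' values and 19 and 18 on the mean of the arrays. Probes above background in both channels turned the balance to 1 and 7 with B. infantis, 4 and 10 with B. bifidum and 3 and 5 with B. adolescentis, and gave 1 and 0 with 4 species and 29 and 4 in culture, where the mean of the probes gave 77 and 11. With B. breve genes centred on each array the splits were 32 and 24, 48 and 38, and 38 and 47 in the comparisons with 1 added species. The median over genes moved by up to 0.61 (median centring, B. infantis) and by -0.30 in the authors' values for culture. The added species' probes gave -0.0534 with processed signals for B. bifidum, and with a filter on dim probes -0.081 for B. bifidum and -0.0926 for B. adolescentis. In culture, where no species was added, the probes of the 3 absent species went from 0.699 to 0.36 with that filter. Of 219 values of the named genes under alternatives 0 changed sign, 151 moved by less than the SD of the arrays and 68 by more. The 151 include values fixed by construction. The size rule on the mean of the arrays leaves a value as it is. Leaving out 1 array moves it by less than that SD and keeps its sign. Values that an alternative removed are not among the 219. With probes above background in both channels only BrMilk_1789 kept a value, and without probes matching other species BrMilk_0218 and BrMilk_1546 had none. Of the 219 values, 10 were under 1 in size, of which 8 without the filter on dim probes and 2 in the authors' deposited values. Over 1.5 times moved 39, of which 17 in the authors' deposited values and 16 without the filter on dim probes. Alternatives for the gene lists were not run, as no list could be matched. No paired analysis was possible because each comparison was 1 sample and the results come from no test. Low signal over background in mouse-derived RNA limits all comparisons.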

Other observations

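In the culture signals the probes of a gene agreed more for B. infantis than for the other absent species. After GC adjustment the intraclass correlation of the probes of a gene in the culture channels was 0.056 and 0.092 for B. infantis, -0.0077 and 0.0042 for B. bifidum, and 0.0196 and 0.0226 for B. adolescentis, beside 0.137 and 0.173 for B. breve. On the ratios of mice against culture B. infantis and B. adolescentis were closer, at 0.0637 ± 0.0112 (bootstrap SD) and 0.0504 ± 0.0151. B. bifidum had 0.00901 ± 0.0109 there. B. breve had 0.0629 ± 0.0113 and so did not exceed B. infantis. In mice against culture, the neighbours' correlation of B. infantis genes was 0.09 across 1685 pairs, outside the shuffled range of -0.05 to 0.05. That of B. bifidum genes was 0.06, just outside its range of -0.06 to 0.05, and that of B. adolescentis genes 0.02, within its own. In the comparisons between mouse-derived RNAs that of B. breve genes lay between -0.06 and 0.06, within the shuffled ranges. In mice against culture 7 B. breve genes with mean log2 ratios of -1 or less lay in 2 runs of at least 3 consecutive numbers, where 1000 shuffled orders had a median of 0 runs and at most 2. The 73 genes of that comparison with mean ratios of 1 or more, counted on the mean alone, lay in 0 such runs, as did the higher and the lower genes of the 4 other comparisons.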
